A study of Caenorhabditis elegans with 2 samples.

How the data were processed

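Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on L4 larvae of Caenorhabditis elegans, the last larval stage before adulthood. Per the labels, the strain carried an integrated transgene that expresses the protein ZK546.5 with a C-terminal GFP-FLAG tag, in an unc-119 mutant background. There were 2 samples, labelled as biological replicates 1 and 2 of a single group, taken from mixed-sex larvae and fragmented by sonication. No second stage, strain or treatment was part of the series, so the comparisons were made within this group: between the replicates, and between reproducible and other peaks. A control experiment is named in the labels, and its reads were not analysed here.

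The data were 4 peak lists in each of 2 genome builds, ce11 and ce10. Per the text files deposited with the lists, the list of each replicate was made from the alignments of that replicate and 1 control file, and the pooled list from the alignments of both replicates. The reproducible list was derived from these by the authors by thresholding on the irreproducible discovery rate (IDR), a measure of how far the ranks of peaks agree between replicates. The aligner, the peak caller and their versions are not given in the sources used here. Each deposited list gives a signal value per peak, which is the authors' own value and was used to describe and rank peaks within a list. The scaling of the signal between lists is not given in the sources used here, so levels were not compared between replicates. The deposited lists also carry a column that by their file format is the −log10 q of the peak. It was at its list's highest value, 2.91, in all 304 reproducible peaks and in 411 pooled peaks in ce11, so it could not rank them and was not used. The summit was taken from the last column of each list. Every replicate and pooled list held exactly 30000 peaks, so the length of these lists carries no measurement, and nearly all peaks of a list had 1 width, 344 bp for 29937 of the pooled peaks. Read numbers are not part of these lists, so the sequencing depth was unknown.

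The ce11 lists were used with the WBcel235 genome, which is the same build, and with Ensembl gene annotation release 115. Every peak ended within the lengths of the WBcel235 chromosomes. The ce10 lists were used for counts, overlaps, the correlation and shares per chromosome, and no coordinate was moved between builds. Positions below are 1-based ce11 positions. A transcription start stands for the annotated 5′ end of any transcript of a gene. Many C. elegans transcripts are trans-spliced, so an annotated 5′ end can lie downstream of the true start. A summit was placed by the annotation at its base, in the order 5′ UTR, coding exon, 3′ UTR, other exon, intron and intergenic.

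Replicates were compared by the share of the 304 strongest peaks of one list with a summit within 100 bp among the 304 strongest of the other, against 1000 random placements within chromosomes. Spearman's rho and Pearson's r of log2 signal were taken across reproducible peaks matched within 100 bp in both replicates, with 100000 permutations. The correlation is across peaks, and peaks are not independent replicates. Shares of peaks near a start and per chromosome were tested with two-sided Fisher's exact tests against the 29653 pooled peaks that overlap no reproducible peak. The authors label the pooled list as peaks and background for input to the IDR, so its weaker entries need not be binding sites. Comparisons with the other pooled peaks are therefore in part comparisons with background. The 28 gene lists, defined by gene symbol or gene type, were tested with one-sided Fisher's exact tests. A gene was called bound when an annotated 5′ end lay within 500 bp of a reproducible summit, which describes position and not regulation. The background was the 14998 genes with any pooled summit within 500 bp, since these could have been called. It included 4221 piRNA genes, of which 7 were bound. Their presence lowers the numbers expected for the other lists and raises their odds ratios. A background of protein-coding genes alone was not run. For sequence, 200 bp windows centred on summits were scanned on both strands for 22 fixed motifs and for all 6-mers with reverse complements joined. Background windows came from the other pooled peaks, matched in bins of 2 percentage points of GC content with up to 10 windows per peak. P-values of each family were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. Confidence intervals of shares are Wilson intervals at 95%, and they cover the counting of peaks only. P-values over peaks or genes describe this pair of replicates and do not carry the spread between further cultures.

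The tests, gene lists, motifs and alternatives were fixed before the data were examined, and alternatives chosen later are named as such. Genes were named by a rule fixed at the same time. It took the gene with the 5′ end nearest to each of the 25 strongest reproducible summits if within 1000 bp, ZK546.5 and unc-119, up to 4 bound members of each gene list by signal, and the 5 motifs and 5 6-mers of smallest p. The alternatives were other distances, backgrounds, window widths and matching rules, the ce10 lists, the 152 strongest peaks alone, and each replicate alone. A setting without a replicate used the 304 strongest peaks of the other replicate against the rest of its list. The tests were tested on simulated data. In 100 random draws of 304 pooled peaks the test of starts called 4 draws, the 28 list tests made 5 calls in all and the 6 chromosome tests made 5. With 60% of peaks placed near starts, 20 ribosomal protein genes added or 30% of peaks placed on chromosome I, each test found the planted difference in 100 of 100 draws. In 5 draws the test of 6-mers made 0 false calls and ranked a 6-mer planted in 20% of windows first in 5 of 5. Random draws share the signal, GC content and nearness to starts of the whole pooled list, whereas the reproducible peaks differ from it in each. The false calls therefore describe the tests without such differences and not the effect of these differences on the real comparisons. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.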

Results

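Binding of tagged ZK546.5 was measured by ChIP-seq in 2 biological replicates of whole L4 larvae, and the question addressed was where in the genome the protein sits. The reproducible list held 304 peaks in ce11. Its strongest peak lay at chromosome I:14469136-14469555 in the intergenic stretch between ekl-4 and the ribosomal protein gene rps-20, with a signal value of 1668. The next were at I:536609-537108 over an exon of the non-coding RNA gene Y65B4BR.10 (signal 1250), and at I:12966702-12967171 (1016), 140 bp upstream of the alpha-tubulin gene tba-2. The fourth lay at I:9625843-9626290 (1006), 163 bp upstream of hsr-9, and the fifth at V:10897171-10897582 (992), 238 bp upstream of sec-61.G, a subunit of the protein translocon. Signal fell steeply with rank: 58 peaks had a signal of 100 or more, the median was 48.2 and the lowest 32.2. The 304 peaks were exactly the 304 of highest signal among the 30000 pooled peaks, 1.01% of that list. Comparisons of reproducible with other pooled peaks are therefore also comparisons of the strongest with weaker peaks. The ce10 list held 296.

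The 25 strongest reproducible peaks each had an annotated 5′ end of a protein-coding gene within 1000 bp, and 22 of the 25 summits were intergenic. The summit near eef-2, which encodes translation elongation factor 2, was 7 bp upstream of its 5′ end (signal 810), and that near icd-2, a subunit of the nascent polypeptide-associated complex, was 343 bp upstream (945). The summit near ubl-1, which encodes a fusion of a ubiquitin-like protein with a ribosomal protein, was 210 bp upstream (439). Others lay near atp-1, the alpha subunit of ATP synthase (870, summit 2 bp upstream), ant-1.1, an adenine nucleotide translocase (535, 53 bp), wapl-1, a cohesin release factor (639, 167 bp), sqd-1 (914, 304 bp), ntl-2 of the deadenylase complex (519, 392 bp), the transcription elongation factor gene elof-1 (440, 29 bp) and the spliceosome gene prp-8 (363, 289 bp). The summit at ash-2 (728) lay inside the gene, in an exon outside annotated coding and UTR parts, 106 bp upstream of an internal 5′ end. The rest of those nearest to a protein-coding gene were at dpm-3 (715, 244 bp), egl-30, a G protein alpha subunit (671, 63 bp), tmem-107 (579, 50 bp) and rheb-1 (440, 270 bp). At 6 of the 25 peaks the nearest 5′ end belonged to a small or non-coding RNA gene, namely Y65B4BR.10, cel-mir-5549, C08F8.13, AH9.7, the piRNA gene 21ur-13751 and Y82E9BR.27. The nearest protein-coding genes there were wwp-1, rfc-4, F01G4.6, rpl-11.2, vig-1 and Y82E9BR.3, at 152 to 421 bp.

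The 25 strongest peaks were found by both replicates, each within the 28 strongest peaks of replicate 1 and the 27 strongest of replicate 2. The peak between ekl-4 and rps-20 and the peak at Y65B4BR.10 ranked first and second in both. Across the 275 reproducible peaks matched in both lists, Spearman's rho of signal was 0.653 and Pearson's r of log2 signal was 0.872, each with a permutation p of 1e-05, the smallest that 100000 permutations can give. These peaks came from the list that the authors thresholded on the IDR, and each needed a match in both replicate lists. These p-values therefore do not test agreement independently. The order was close among the 50 strongest peaks, with a rho of 0.975, and looser among the other 225, with a rho of 0.370, a split chosen after the values were seen. Of the 304 strongest peaks of replicate 1, 143 (47.0%, 95% interval 41.5 to 52.7%) had a summit within 100 bp of one of the 304 strongest of replicate 2. Random placement gave a mean of 0.0645% and at most 1.32% in 1000 placements (permutation p = 0.001, the smallest they can give). Among the top 608 of each list the share was 30.9%, and among the top 1520 it was 17.7%. Of the reproducible peaks, 95.1% had a match anywhere in the list of replicate 1 and 95.4% in that of replicate 2, and 71.4% and 61.5% had one among the 304 strongest.

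**Figure D1:**
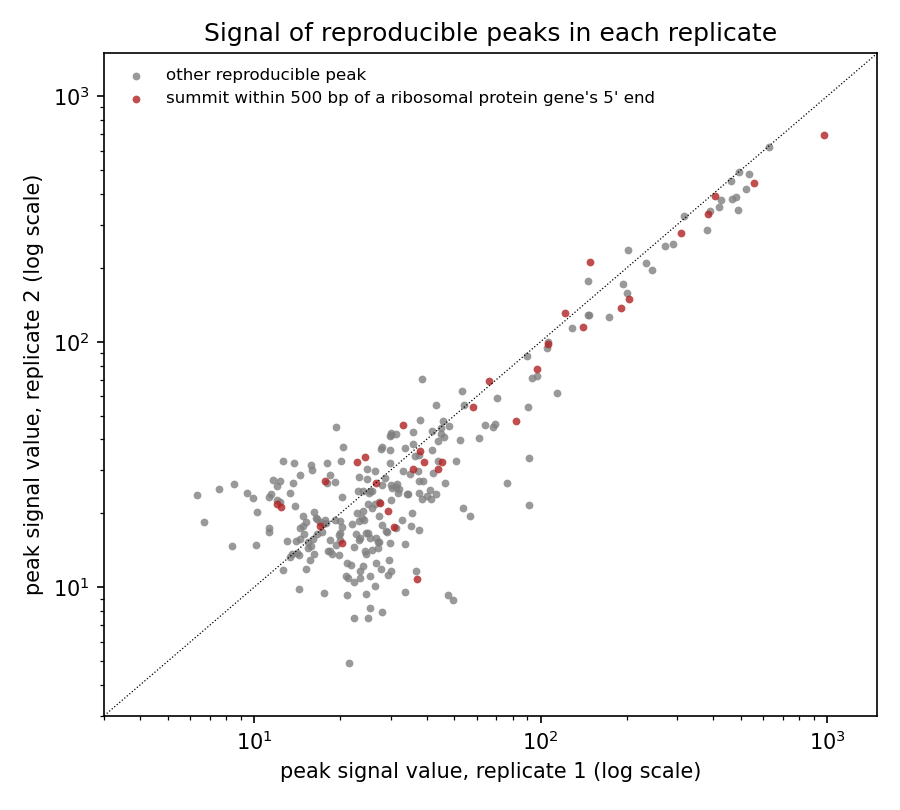
Signal value of each of the 275 reproducible peaks matched in both replicates, with replicate 1 on the horizontal and replicate 2 on the vertical axis, both on log scales. Each point is a peak, red where the summit lies within 500 bp of a ribosomal protein gene's 5′ end, and the dotted line marks equal values; the points tighten towards the strongest peaks, whose rho was 0.975 for the top 50.

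Reproducible peaks lay mostly in promoter regions. Of the 304 summits, 212 (69.7%) were intergenic, 33 in introns, 33 in exons outside annotated coding and UTR parts, 12 in 5′ UTRs, 9 in coding exons and 5 in 3′ UTRs. Among the 29653 other pooled peaks 34.1% were intergenic, 35.5% in introns and 20.4% in coding exons. A 5′ end lay within 500 bp of 233 reproducible summits (76.6%, 71.6 to 81.1%) and of 37.5% of the others, an odds ratio of 5.47 (two-sided Fisher's exact test, p = 2.26e-43). Random positions on the same chromosomes reached 33.0%, not far below the share of the other pooled peaks. The excess was smaller against the next 304 pooled peaks by signal, of which 63.5% were near a start (odds ratio 1.89, Fisher's exact p = 0.000534). With the 304 strongest peaks of replicate 2 alone the share was 64.5% and the odds ratio 3.04.

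Chromosomes I and III held more reproducible peaks than the background and chromosome V fewer. Chromosome I held 71 peaks (23.4%, 18.9 to 28.4%, against 16.2% of the other pooled peaks; odds ratio 1.58, Fisher's exact test, adjusted p = 0.00389). Chromosome III held 66 (21.7%, 17.4 to 26.7%, against 15.3%; odds ratio 1.54, Fisher's exact test, adjusted p = 0.00594). Chromosome V, which carries many chemoreceptor genes, held 25 (8.22%, 5.63 to 11.9%, against 18.7%; odds ratio 0.389, Fisher's exact test, adjusted p = 3.20e-06). The 43 peaks on II, 54 on IV and 45 on X did not pass two-sided Fisher's exact tests (adjusted p from 0.479 to 0.820). The call for chromosome III ended in the exact test with the 152 strongest peaks (33 peaks, odds ratio again 1.54, adjusted p = 0.0635) and without replicate 1 (odds ratio 1.23, adjusted p = 0.377).

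**Figure D2:**
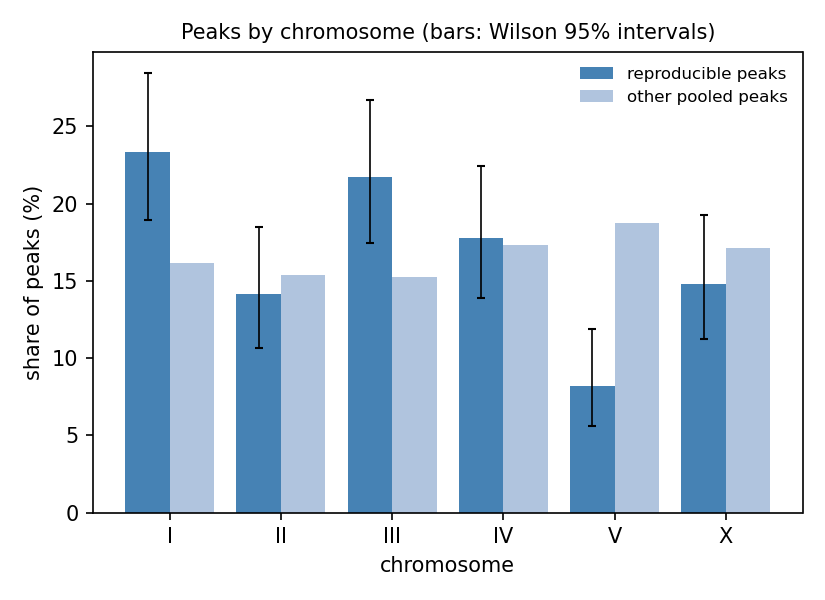
Share of peaks in percent (vertical axis) on each of the 6 nuclear chromosomes (horizontal axis), in blue for the 304 reproducible peaks with Wilson 95% intervals and in grey for the 29653 other pooled peaks. Chromosome V held 8.22% of reproducible peaks and 18.7% of the others.

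Genes of cytosolic ribosomal proteins were the list with the most members within 500 bp of reproducible peaks. Of the 72 members with a pooled peak near a 5′ end, 37 were bound, by 35 distinct peaks, where 1.89 were expected (odds ratio 43.3, one-sided Fisher's exact test, adjusted p = 2.91e-38). The strongest were rps-20 (signal 1668, summit 245 bp from the 5′ end), rps-19 (1006, 282 bp), rpl-11.2 (797, 369 bp) and rps-23 (715, 290 bp). These 35 peaks were 11.5% of all reproducible peaks. At each of the 4 strongest another gene's 5′ end was nearer to the summit (ekl-4, hsr-9, AH9.7 and dpm-3). Members bound numbered 5 of 11 within 200 bp, 15 of 36 with 1 nearest gene per peak, 32 without replicate 1 and 33 without replicate 2, each past the threshold.

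Other groups of protein synthesis, folding and energy supply were bound more often than expected, in smaller numbers. Of 31 translation factor genes 6 were bound against 0.812 expected (odds ratio 9.04, Fisher's exact test, adjusted p = 0.000737), with eef-1A.1 (signal 849), eef-2 (810), iff-2 (304) and eif-3.C (82.5) the strongest. The summit at eef-1A.1 was 389 bp from its 5′ end and nearer to those of cel-mir-5549 (16 bp) and rfc-4 (152 bp). Of 35 chaperone genes 7 were bound against 0.917 expected (odds ratio 9.44, Fisher's exact test, adjusted p = 0.000201). They included dnj-12 (107), the chaperonin genes cct-1 (98.2) and cct-8 (63.5), and dnj-14 (63.0). Of 33 genes of the respiratory chain and ATP synthase 6 were bound against 0.865 expected (odds ratio 8.37, Fisher's exact test, adjusted p = 0.000884), led by atp-1 (870), cox-5B (118), cox-5A (78.4) and cox-6B (68.4). The chaperone call ended within 200 bp and with 1 nearest gene per peak (2 members bound under each, adjusted p of 0.226 and 0.350), and the respiratory call with 1 nearest gene per peak (3 members, 0.0554).

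Genes of spliced leader and small nucleolar RNAs (snoRNAs) were also over-represented. Of 15 spliced leader RNA genes with a pooled peak nearby, 6 were bound, by 6 peaks, against 0.393 expected (odds ratio 25.1, Fisher's exact test, adjusted p = 1.48e-05). They were of the sls-2 family, which encodes the leader spliced onto downstream genes of operons. The strongest were sls-2.2 and sls-2.3, which shared their strongest peak (signal 74.5), sls-2.4 (73.3) and sls-2.1 (69.5). The snRNA list held these same 6 genes and F38E11.11 (32.2), 7 of 54 in all (Fisher's exact test, adjusted p = 0.00197), and its call ended without replicate 2 (4 members, adjusted p = 0.147). Of 165 snoRNA genes 17 were bound by 16 peaks, against 4.32 expected (odds ratio 4.42, Fisher's exact test, adjusted p = 1.48e-05). At 5 of the 17 the peak was also near a gene of the ribosomal protein list. The strongest were F39B2.14 (579), H06I04.9 (439), F54E7.10 (134) and Y24D9A.9 (83.1). H06I04.9 lies within ubl-1 and shares its peak. That gene encodes a ribosomal protein fusion but is not on the list, so each of these strongest peaks was near a gene that encodes a ribosomal protein. In the same exact test, the snoRNA call ended within 200 bp (adjusted p = 0.0564), with 1 nearest gene per peak (0.137) and with the 152 strongest peaks (0.149).

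A harder background left 1 of the 7 calls, which count the nested snRNA and spliced leader lists separately. With genes near the 2000 strongest pooled peaks as the background, a setting chosen after the data were seen, the ribosomal protein genes passed with an odds ratio of 7.84. The other 6 lists had odds ratios from 1.39 (snoRNA genes) to 5.02 (spliced leader RNA genes) and 6.70 (translation factors, 6 of 9), and adjusted p from 0.0930 to 0.670 in the exact test. With the 35 peaks near ribosomal protein genes left out, also chosen later, those 6 lists passed, and the proteasome list as well (adjusted p = 0.0476 in the exact test). The peak at ubl-1 was not among the 35, since that gene is not on the ribosomal protein list, so it still counted for the snoRNA genes.

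Lists tied to single tissues, the germline or the environment were not bound beyond expectation. No member was bound of 30 intestine, 13 body wall muscle, 6 pharynx, 39 neuron and 9 epidermis markers, 16 sperm genes, 25 molting and hedgehog-related genes, 75 innate immune genes or 265 chemoreceptor genes. Of the chemoreceptor genes 6.94 were expected and of the others between 0.157 and 1.97 in each list, so 0 bound in these was close to expectation. Vitellogenin and rRNA genes had no member in the background. Of 62 cuticle collagen genes 1 was bound, col-38, under a peak it shared with a ribosomal protein gene. Of 27 germline and meiosis genes 1 was bound (puf-9, signal 83.2), of 46 detoxification genes 1 (gst-43, 42.6), and of 171 transcription factor genes 3 (ceh-38, 55.8; hlh-11, 44.7; zip-2, 39.3). Of 23 proteasome genes 3 were bound (pbs-1, 321; pbs-2, 57.5; rpn-5, 38.9) with an adjusted p of 0.0750, which was 0.00924 with all annotated genes as background and 0.0429 with 1 nearest gene per peak (one-sided Fisher's exact tests). Of 20 histone genes 2 were bound (htz-1, 639, and his-37, 83.7), of 29 splicing genes 2 (prp-8, 363, and prp-40, 35.6), of 84 microRNA genes 3, led by cel-mir-5549 (849), and of 269 tRNA genes 3 against 7.05 expected. Some peaks counted for more than 1 list: that of cel-mir-5549 is also that of eef-1A.1, and that of pbs-2 also served a translation factor gene. The htz-1 summit was nearer to wapl-1 (167 against 309 bp). Without replicate 2 the splicing list passed (5 of 26 genes, Fisher's exact test, adjusted p = 0.00275), and so did the tRNA list (25 of 295, odds ratio 3.24, adjusted p = 1.11e-05), of which 4 of 273 were bound once mitochondrial peaks were also left out, a setting chosen after the data were seen. Of 4221 piRNA genes 7 were bound, where 111 were expected, by 6 peaks, the strongest with 21ur-12279 (870) and 21ur-13751 (783). With the reproducible peaks and the main background all of these lists had an adjusted p of 0.0750 or more in the one-sided test, which does not test for fewer members than expected.

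**Figure D3:**
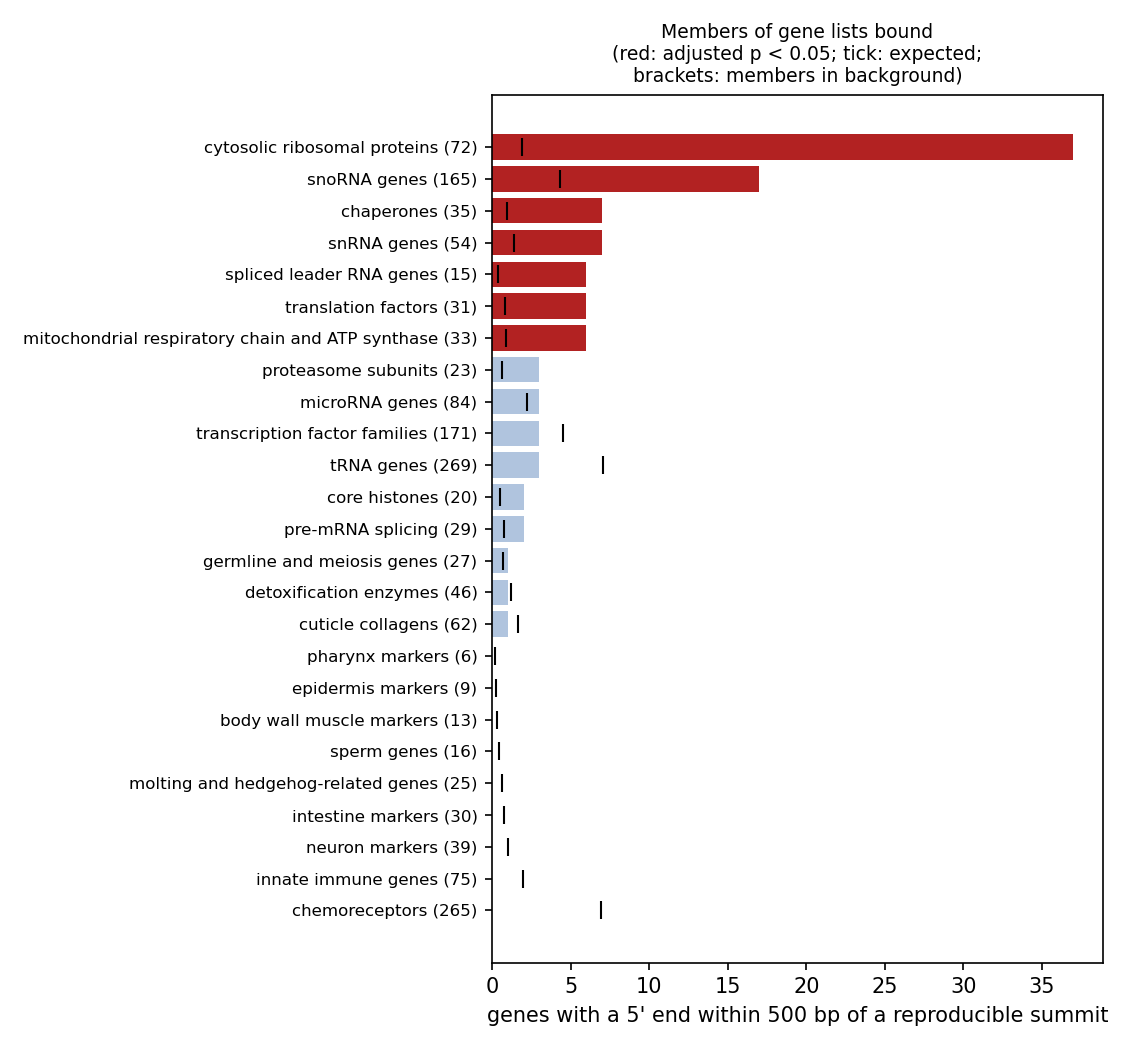
Number of genes of each list with a 5′ end within 500 bp of a reproducible summit (bars, horizontal axis), for the 25 lists with members in the background other than the piRNA genes. Red bars passed the test, black ticks mark the number expected and brackets give the members in the background; the ribosomal protein bar reaches 37 where 1.89 were expected.

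Starts, ribosomal protein genes and the 6-mer ACCGTA were most frequent at the strongest peaks. In ranges of rank chosen after the values were seen, 98.0% (89.5 to 99.6%) of the 50 strongest peaks lay within 500 bp of a 5′ end, then 76.5% of ranks 51 to 152 and 69.7% of ranks 153 to 304. Peaks that were not reproducible reached 56.8% at ranks 305 to 1000 and 35.6% beyond rank 10000. Ribosomal protein genes were near 28% (17.5 to 41.7%) of the 50 strongest peaks, 12.7% of ranks 51 to 152, 5.26% of ranks 153 to 304 and 1.44% of ranks 305 to 1000. ACCGTA was in 31 of the 50 strongest windows and 34 of the other 254 reproducible windows (odds ratio 10.6, two-sided Fisher's exact test, p = 3.55e-12). GCGCAC and TGCGTCTC were not confined to the top: GCGCAC was in 16% of the 50 strongest windows, 26.5% of ranks 51 to 152 and 22.4% of ranks 153 to 304, and TGCGTCTC in 10%, 6.86% and 15.8%.

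**Figure D4:**
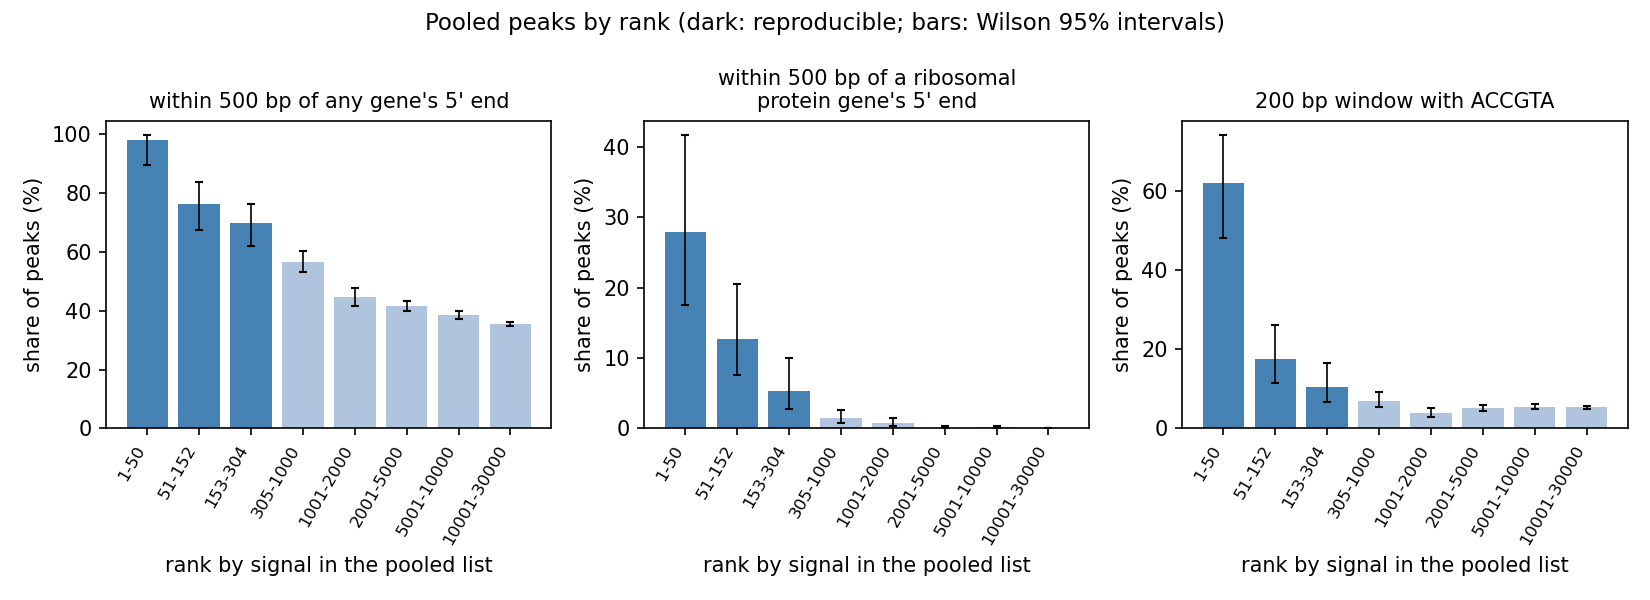
Share of pooled peaks in percent (vertical axes) by range of rank in signal (horizontal axes), for nearness to any 5′ end, nearness to a ribosomal protein gene's 5′ end, and presence of ACCGTA in the 200 bp window. Dark bars are reproducible peaks, error bars are Wilson 95% intervals, and ACCGTA falls from 62% in the 50 strongest peaks to 10.5% at ranks 153 to 304.

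Several short sequences were more frequent under reproducible peaks than in windows of like GC content. The mean GC content of the windows was 43.8%, against 34.8% in all other pooled peaks and 43.4% in the 2980 matched windows. Windows were not matched for nearness to a start. Starts lay within 500 bp of 76.6% of reproducible peaks and of 37.5% of all other pooled peaks. Sequences of bound places therefore cannot be told apart here from sequences common in promoters. Of all 6-mers, 185 were more frequent and 147 less frequent (two-sided Fisher's exact tests). The 5 of smallest p were GCGCAC, in 22.7% of windows against 6.34% (odds ratio 4.34), ACCGTA, in 21.4% against 5.70% (4.50), AGCGCG, in 19.1% against 4.70% (4.78), GAGCGC, in 22.4% against 6.85% (3.92), and ACGCAG, in 26.6% against 9.56% (3.43). Their adjusted p ranged from 1.28e-14 to 5.48e-13, and each passed in every alternative. These words are not independent, since some overlap and can mark the same places. GAGCGC and AGCGCG share AGCGC, and CTGCGT, the reverse complement of ACGCAG, shares TGCGT with TGCGTCTC. Without replicate 1 the number of 6-mers past the threshold was 179.

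Of the 22 fixed motifs 3 passed, all more frequent, with the same lack of matching for nearness to a start. The core promoter word TGCGTCTC was in 11.8% of windows against 4.13% (odds ratio 3.12, Fisher's exact test, adjusted p = 3.65e-06), a GAGA repeat in 16.4% against 9.40% (1.90, 0.00302) and the PHA-4 consensus in 47.4% against 37.3% (1.51, 0.00585). CCAAT (28.3% against 35.6%, adjusted p = 0.0630) and the E2F consensus (7.24% against 4.30%, 0.121) did not pass the exact test. Calls of TGCGTCTC and the GAGA repeat ended with the 152 strongest peaks (adjusted p of 0.263 and 0.757). That of the GAGA repeat also ended in 100 bp windows (0.169), and that of PHA-4 without GC matching (0.541) and without replicate 1 (0.101).

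Close to the tagged gene itself there were fewer pooled peaks than in the median window. ZK546.5 lies at II:4935818-4937974 on the plus strand. Within 25 kb on either side there was no reproducible peak, as in 87.4% of windows of that width, and there were 6 pooled peaks, the strongest with a signal of 19.2, where windows of that width along the genome had a median of 16. The replicate lists held 10 and 11 there, against medians of 15 and 16, and 14.4% and 19.9% of windows had as few. Within 10 kb there was 0 in the pooled list and in both replicate lists, where the median of pooled windows was 7. Around unc-119 (III:10902641-10908935), whose rescuing copy is commonly part of such transgenes, there were 22 pooled peaks within 25 kb against a median of 17, and none was reproducible. The replicate lists went the other way there, with 14 peaks in replicate 1 and 15 in replicate 2, each against a median of 17. As many pooled peaks as at unc-119 were found in a share of 0.186 of windows, and as many as at ZK546.5 in 0.973.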

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

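Mitochondrial DNA carried peaks in the list of replicate 1 alone, and they entered the overlap between replicates and the settings without replicate 2. The list of replicate 1 held 25 mitochondrial peaks in ce11 and 23 in ce10, of which 23 were among its 304 strongest peaks in ce11, and the highest had a signal of 286 and rank 20. The list of replicate 2 and the pooled list each held 0, although the pooled list was made from both replicates and its lowest signal was 7.43. The 25 peaks covered 50.3% of the mitochondrial genome of 13794 bp, whose GC content is 23.8%. ACCGTA occurs 1 time in it and lay within 100 bp of 0 of the 3 strongest mitochondrial summits. Tests of 2 explanations, with outcomes written beforehand, were run and then left out of the tables of tests after their results had been seen: the covered share, set against 50% for a signal over the whole mitochondrial genome, largely follows from the number and width of the peaks, and a word that occurs 1 time leaves little room for a summit near it, so neither test decided anything.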

How the results depend on the processing

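No paired analysis was possible because the series has 1 group. The settings without mitochondrial peaks (alone or together with leaving out replicate 2), without peaks near ribosomal protein genes and with the 2000 strongest pooled peaks as background were chosen after the data were seen. Of the results named in the plan, the number of reproducible peaks, the correlation and the excess near starts kept their direction and their side of the threshold under every alternative run. For the tagged gene the planned share of windows with as many pooled peaks (0.973, and 1 within 10 kb and 0.911 within 50 kb) tests for an excess and cannot show that peaks are few. The share with as few, read only after the values were seen, was 1.44% within 10 kb, 4.09% within 25 kb and 11.2% within 50 kb. The share of matched strongest peaks was 40.8% within 50 bp, 30.9% with 608 and 17.7% with 1520 peaks per list; the longer lists add weaker peaks by construction. Without mitochondrial peaks it was 50.9%. Leaving out a replicate gave odds ratios near starts from 3.04 to 6.67, 2 to 3 chromosomes (III lost its call without replicate 1), 7 to 8 gene lists, 2 to 4 motifs and from 179 to 292 6-mers. The 8 lists without replicate 2 lacked the snRNA genes and gained the splicing and tRNA genes. The tRNA list turned from 3 members bound, fewer than expected, to 25, and was back at 4 once mitochondrial peaks were left out too, so its call rested on mitochondrial peaks; the splicing list kept 5 members and its call. That setting gave an odds ratio near starts of 5.61, 8 gene lists with the proteasome list in place of the tRNA list, 5 motifs and 334 6-mers. With the genes near the 2000 strongest pooled peaks as background 1 gene list passed (odds ratio 7.84, 43.3 in the main setting), and 6 of 7 lists lost their call with odds ratios from 1.39 to 6.70, the highest that of the translation factors (9.04 in the main setting), which had 9 genes left in the background. Without GC matching 10 motifs (8 of them not called with it) and 749 6-mers passed, 100 bp windows gave 201 6-mers, and the 152 strongest peaks gave 1 motif; the causes were not tested. Chromosome IV, never called, turned from an odds ratio of 1.03 to 0.966 in ce10, 0.850 with the 152 strongest peaks and 0.973 without replicate 2 (1.09 without replicate 1), the splicing list, with 2 members bound, to 0 within 200 bp, and the E2F consensus, called only without GC matching, to 0.881 in 100 bp windows. Among the 10 gene lists called in any setting, 5 motifs, 5 6-mers and 6 chromosomes, 159 values kept direction and side of the threshold, 21 lost the call, 9 gained it and 6 reversed. The gains were the proteasome list with all annotated genes as background, with 1 nearest gene per peak, without peaks near ribosomal protein genes and without replicate 2 and mitochondrial peaks, the splicing list in both settings without replicate 2, CCAAT without GC matching and without replicate 2 and mitochondrial peaks, and E2F without GC matching. Other motifs gained calls without GC matching (GATA, the E-boxes, Sp1/KLF, HSE and TATA), without replicate 2 (HSE, Fisher's exact test, adjusted p = 0.0399) and without replicate 2 and mitochondrial peaks (the T-block). Peak lists carry no read numbers, so what depth limits could not be measured.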

Other observations

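The tests of divergent genes, of the 2000 strongest pooled peaks as background and of extra copies around ZK546.5 (where 0 peaks within 10 kb had been seen), the side of the summit and the choice of CCTGC came after the values had been seen, and the other tests of explanations were written before their results. Reproducible peaks often lay near the 5′ ends of divergent genes. Of the 198 summits within 500 bp of a protein-coding 5′ end, 75 (37.9%, 31.4 to 44.8%) had both 5′ ends of a head-to-head pair within 500 bp. Among 7854 other pooled peaks the share was 6.60% (odds ratio 8.64, two-sided Fisher's exact test, p = 2.08e-35). The count did not require the summit to lie between the paired ends. The peak between ekl-4 and rps-20 had such a pair. All 35 summits near ribosomal protein genes lay upstream of the nearest protein-coding 5′ end, which was not always that of the ribosomal protein gene, at a median of 249 bp (quartiles 153 and 312 bp); to the ribosomal protein gene's own 5′ end the median was 297 bp (247 and 358 bp), with all 35 upstream. Of the other 163, 140 (85.9%) lay upstream, and the median distance was 167 bp (74.5 and 269 bp).

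The word ACCGTA marked the strongest peaks. It was in 31 of the 50 strongest windows (62%, 48.2 to 74.1%), in 13.4% of the other 254 reproducible windows and in 5.70% of GC-matched windows. Shuffles that keep each window's dinucleotides gave a mean of 4.50% and at most 18% over 1000 shuffles, so base composition does not account for it. The 50 strongest peaks of replicate 1 carried it in 54% and those of replicate 2 in 62%, so it does not rest on 1 replicate, and 0.816% of the 1225 pairs of peaks shared a 16-mer in their flanks, which argues against copies of 1 repeat. Of the 5 6-mers of smallest p on chromosomes I to III, 4 were more frequent on IV, V and X at p under 0.01, ACCGTA among them (15.3% against 4.15%, Fisher's exact p = 5.74e-06), which argues against the choice of the word on the same peaks. Near the 5′ ends of ribosomal protein genes the word was no more frequent at bound members than at others (odds ratio 0.798). That the word is part of a sequence recognised by ZK546.5 is a hypothesis, since it may also mark strong promoters of another kind, and no biological explanation was tested.

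A longer sequence was looked for around ACCGTA, with CCTGC as its second part. Of the matches within 500 bp of the 50 strongest summits, 29 of 34 (85.3%) lay within 50 bp of the summit, and 31.1% at the other peaks. CCTGCA was in 50% of the 50 strongest windows and 3.29% at ranks 153 to 304. On chromosomes I to III, 6 peaks had CCTGC on the same strand with its first base 16 bp after that of ACCGTA, the most common spacing among 13 pairs from 6 to 40 bp apart. On IV, V and X there was 1 such peak among 3 pairs (permutation p = 0.0844), so the p under 0.05 asked for beforehand for a fixed spacing of a longer sequence was not reached. Of the 5 places on IV, V and X with the pair at that spacing, 1 (20%) lay within 100 bp of a reproducible summit, against 0.901% of 222 pairs at other spacings (p = 0.0649, two-sided Fisher's exact test). Both results met the outcome written beforehand as counting against the hypothesis, p of 0.05 or more; that rule was set aside only after the results were seen, because 3 pairs and 5 places are too few for a missed threshold to show absence, so neither the spacing nor that the pair marks bound places was shown, and on I to III, where the spacing was chosen, 6 of 15 were bound.

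Ribosomal protein genes at reproducible peaks were weighed against a pair of explanations. An excess shared equally by promoters near the 2000 strongest pooled peaks would vanish with their genes as background. The odds ratio was then 7.84, past the threshold, which goes against an equal excess only. An excess that grows with signal would not vanish there, since the reproducible peaks are the strongest of the 2000. The test therefore cannot decide on an excess of that kind. Transcription of these genes whatever their sequence, as a technical source of signal, stays open. The outcome written beforehand for it was that the share with ACCGTA does not differ between bound and other members, and no difference was found. The word, within 500 bp of a 5′ end, was carried by 18 of 37 bound members and 19 of 35 others (odds ratio 0.798, two-sided Fisher's exact p = 0.646). The Wilson intervals of these shares, 33.4 to 64.1% and 38.2 to 69.5%, are wide and leave room for a difference in either direction. The word was also sought around 5′ ends and not at summits. A missed threshold with so few genes does not show equal shares, so the test does not decide on transcription. For CCTGCA the counts were 14 of 37 and 6 of 35 (odds ratio 2.94, exact p = 0.0668). Control or untagged chromatin, which could separate transcription from binding, was not analysed here, and no biological explanation was tested.

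A long stretch without peaks surrounded ZK546.5. It spanned 32 kb in the pooled list (II:4920954-4952961, between summits), 25.4 kb in replicate 1 and 33.8 kb in replicate 2, where the median gap between summits was 2145 to 2222 bp. Gaps as long made up 0.0967% of those in the pooled list, 0.227% in replicate 1 and 0.0867% in replicate 2. These are shares of gaps, and a given gene falls in a long gap more often than in a short one. They therefore overstate how rare the stretch is. Windows as wide as the gene with 10000 bp on either side held no pooled peak in 1.44% of cases. For replicate 1 this was 0.951%, and for replicate 2 it was 1.21%. The longest 1% of gaps, used below, is also a share of gaps. Extra copies of the region in the transgenic strain, taken out with the control or a filter, may be the source: each stretch exceeded 20 kb and was among the longest 1% of gaps, while the ends differed by up to 4920 bp, more than the 2 kb set for the test, so it left it open. Repeated sequence could not be excluded either, since 11.8% of the 36-mers of the common stretch occur more than once in the genome, between the 5% and 20% set beforehand, and no biological explanation was tested.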
